A study of Homo sapiens with 15 samples.

How the data were processed

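RNA from 5 human cell lines was sequenced, with 3 libraries per line. Per the labels' protocols, total RNA was taken up in TRIzol and treated with DNase I, cDNA was primed with random hexamers, the libraries went through 15 cycles of PCR, and read pairs of 150 bases were sequenced. The protocols name 2 Illumina platforms and do not say which library ran on which, so a platform difference was not tested. The authors deposited gene-level TPM values with 2 decimals for 60666 Ensembl gene IDs in 15 library columns. Per the submitters' processing notes, fastp, HISAT2, StringTie, RSEM, DESeq2, edgeR and limma were used, with no version, role or order given. The genome build and annotation release are not given in the sources used here, so no coordinates are printed. The deposited columns of line means (5) equalled the means of the library columns within 3.33e-07 TPM and entered no test.

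TPM divides by transcript length and by the library's total, so each gene is a share of its library. A few abundant genes can therefore lower the values of all others, and TPM keeps no depth. The library sums ran from 976280 to 995969 TPM. Because no read depth is recorded, precision was judged from the spread between libraries alone. The design had been written for counts. As the values were TPM, the planned edgeR test was not used and a test on the log scale took its place.

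Genes with at least 1 TPM in at least 3 of the 15 libraries were tested, 16491 of 60666, of which 13509 were protein-coding and 161 short RNA. Symbols were as deposited by the authors. GENCODE 29, which need not be the authors' release, served only for biotype, exonic length and the order of neighbouring genes, and held 96.3% of the IDs and 99.1% of those tested. The symbol of 1289 IDs is shared with another ID, so IDs are printed with the leading genes. The strand setting of the counting is not stated, so antisense and overlapping genes were not named.

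The main test was limma 3.58.1 with an intensity trend on log2(TPM + 1), fitted to all 15 libraries with 1 mean per line and 10 residual degrees of freedom. A gene was called where the Benjamini-Hochberg adjusted p was under 0.05 and the change at least 2-fold. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes. Tests were two-sided, except the one-sided counts of neighbouring pairs and of regroupings. Each cancer line was compared with SV-HUC-1 and with the other cancer lines (6 pairs). Genes called in 1 direction in all 4 lines, or against all other lines, were counted. Tools were R 4.3.3 with data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

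The groups, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls among called genes with a symbol of their own, values that did not overlap between the lines and a mean of at least 10 TPM in the higher line. It also took 12 genes each way called in all 4 lines, 5 each way set apart in a line, up to 3 called members each way of each list, and a fixed set of bladder cancer and urothelial genes. Where many qualified, the text prints some of them, and some are not reported here. Genes with all libraries of a line at 0 are said to be listed at 0 and given no fold, since a 0 without counts can be a failed estimate.

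The 28 gene lists were luminal urothelial, basal and squamous, epithelial junction, mesenchymal, interferon-stimulated, MHC class I presentation, cytokine and NF-kB, cell cycle, p53 targets, MAPK output, TGF-beta and YAP output, hypoxia and glycolysis, NRF2 targets, cholesterol synthesis, fatty acid synthesis, unfolded protein response, cancer-testis antigens, HOX genes, proteases, androgen, oestrogen and retinoid handling, bladder cancer drivers, nuclear oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, and markers of immune, endothelial, fibroblast and muscle, and neuroendocrine cells. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, with adjustment over all lists and comparisons of a family. Camera compares a list with all other genes, whose median lay below 0, so its direction can differ from the sign of the list's own median.

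Calling was tested on data simulated for T24 against SV-HUC-1 (16491 genes). It recovered 78% of 100 genes changed by 1.5 log2 and 96% of 100 by 2.5 log2, and called 0.0368% of unchanged genes. The rates were not split by level and may not hold for low genes. Alternatives were other scalings, pseudocounts, filters, thresholds and tests, the replicate number as a block, and each library left out in turn. Those chosen after seeing the data are named below. Levels of XIST and of Y-linked genes were left out.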

Results

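Expression was measured by RNA sequencing of total RNA from 5 human cell lines, 3 libraries each and 15 in all. SV-HUC-1, a urothelial line immortalised with SV40, was the reference, and 5637, UMUC3, T24 and J82 were derived from bladder cancers. No normal urothelium was sequenced, so changes, also of cell cycle genes and p53 targets, may stem from immortalisation. The question was which genes differ between each cancer line and SV-HUC-1, and which of these the cancer lines share. TPM keep no depth, so the reads behind a value are unknown and no counting interval is given. The labels do not say that the 3 libraries of a line came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

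Between 12688 and 14880 genes reached 1 TPM per library. Libraries of the same line correlated across genes at r = 0.952 to 0.988 over 15 pairs, and libraries of different lines at 0.795 to 0.862 over 90 pairs, where genes are not independent replicates. The third library stood farthest from its line mean in T24 (SD of the deviations 0.470 log2), J82 (0.436), 5637 (0.395) and SV-HUC-1 (0.326), against 0.234 in the closest library. Short RNA held 7.59% of the TPM in the first 5637 library against 1.63% and 1.70% in the other 5637 libraries, and the mitochondrially encoded genes held 3.50% to 8.94% over all libraries. Of the markers of cell types other than epithelium, 6 of 20 immune, 3 of 12 endothelial, 8 of 15 fibroblast and muscle and 6 of 14 neuroendocrine genes passed the filter of 1 TPM in 3 libraries.

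Against SV-HUC-1, 1623 genes were higher and 2870 lower in 5637, 1460 higher and 4906 lower in UMUC3, 1364 higher and 3873 lower in T24, and 1550 higher and 3476 lower in J82, of 16491 genes tested (limma, adjusted p under 0.05 and at least 2-fold). Higher calls made up 36.1%, 22.9%, 26.1% and 30.8% of the calls in these lines. The median log2 fold change of all genes was -0.18, -0.50, -0.36 and -0.30, and median-of-ratios scaling moved these medians to 0.01, -0.04, -0.02 and -0.01 and the share of higher calls to 50.9%, 48.0%, 48.2% and 49.3%, so directions are relative to the scaling. The counts with that scaling were 2097 higher and 2025 lower in 5637, 2576 and 2790 in UMUC3, 2231 and 2398 in T24 and 2218 and 2277 in J82. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1.

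**Figure D1:**
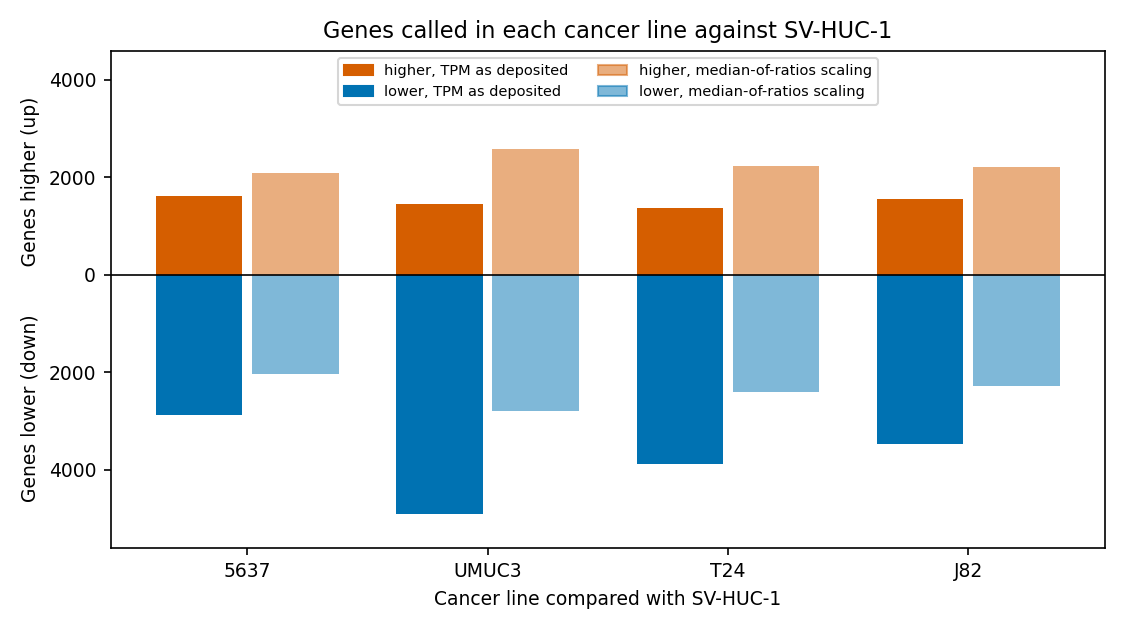
Number of genes called higher (upward bars) and lower (downward bars) in each cancer line than in SV-HUC-1, for TPM as deposited and after median-of-ratios scaling. In UMUC3, 1460 genes were higher and 4906 lower as deposited, against 2576 and 2790 after scaling.

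In 5637, 19 of 35 cytokine and NF-kB genes and 16 of 27 basal and squamous genes were higher than in SV-HUC-1, calls lost with an estimated correlation (adjusted p = 0.658 and adjusted p = 0.0693). The iron-scavenging lipocalin LCN2 (ENSG00000148346) rose most, from 6.7 ± 1.15 to 5967 ± 2070 TPM (log2 fold change 9.54, SE 0.85, adjusted p = 6.35e-07). The collagenase MMP1 (ENSG00000196611) rose from 0.113 ± 0.0751 to 419 ± 34.4 TPM (log2 fold change 8.56, SE 0.67, adjusted p = 1.8e-07). The calprotectin subunit S100A9 (ENSG00000163220) from 14.1 ± 3.24 to 5361 ± 2500 TPM (log2 fold change 8.36, SE 0.34, adjusted p = 2.45e-10) rose with its partner S100A8 (429.8 TPM, log2 fold change 8.1). The stromelysin MMP10 (ENSG00000166670) was listed at 0 in the SV-HUC-1 libraries and at 338, 434 and 142 TPM in those of 5637. The antiviral tether BST2 (ENSG00000130303) fell furthest, from 596 ± 39.3 to 0.17 ± 0.294 TPM (log2 fold change -9.02, SE 0.34, adjusted p = 1.07e-10). The translation elongation factor EEF1A2 (ENSG00000101210) fell from 1383 ± 73.4 to 1.83 ± 0.641 TPM (log2 fold change -8.96, SE 0.31, adjusted p = 4.92e-11). The interferon-induced IFI27 (ENSG00000165949) from 875 ± 200 to 0.817 ± 0.438 TPM (log2 fold change -8.91, SE 0.24, adjusted p = 5.53e-12) and the matrix protein SPARC (ENSG00000113140) from 801 ± 77.4 to 0.707 ± 0.40 TPM (log2 fold change -8.9, SE 0.20, adjusted p = 1.15e-12) fell as well. The hair keratin KRT81 (0.11 TPM, log2 fold change -8.66) and the serine proteases KLK5 (0.283 TPM, log2 fold change -8.21) and KLK6 (0.27 TPM, log2 fold change -8.08) also fell. The glutamate transporter SLC1A6 (ENSG00000105143) was at 227 ± 78.6 TPM in SV-HUC-1 and listed at 0 in 5637. Values are mean ± SD of 3 libraries. The 3 values of these genes did not overlap between the lines.

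Among the cancer genes fixed in advance, the retinoblastoma gene RB1 (ENSG00000139687) fell from 28.9 ± 4.21 to 0.873 ± 0.27 TPM (log2 fold change -4.0, SE 0.30, adjusted p = 1.18e-07). The cell cycle transcription factor E2F3 (ENSG00000112242) rose from 18.2 ± 0.367 to 168 ± 7.19 TPM (log2 fold change 3.13, SE 0.17, adjusted p = 2.88e-09). The cyclin gene CCND1 fell from 213 to 30.4 TPM (log2 fold change -2.79, SE 0.20, adjusted p = 6e-08). The inhibitor gene CDKN2A rose from 379.6 to 1020 TPM (log2 fold change 1.43, SE 0.22, adjusted p = 0.000109). The epithelial adhesion gene EPCAM fell from 255 to 64.3 TPM (log2 fold change -1.99, SE 0.20, adjusted p = 2.07e-06). E-cadherin CDH1 was at 71.1 ± 5.28 TPM in SV-HUC-1 and 53.5 ± 7.64 TPM in 5637, which did not pass the test (log2 fold change -0.41, adjusted p = 0.213). The intermediate filament gene VIM fell from 313 to 70.6 TPM (log2 fold change -1.98, SE 0.35, adjusted p = 0.00034).

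By group, 16 of 27 basal and squamous genes were higher in 5637 and 2 lower (median log2 1.48), among them the cornified envelope gene SPRR1B (141 TPM, log2 fold change 6.72). For basal genes camera gave adjusted p = 8.46e-08, and adjusted p = 0.0693 with an estimated correlation. Of 35 cytokine and NF-kB genes 19 were higher and 3 lower (median log2 1.57), with IL1B (387 TPM, log2 fold change 7.05) and the prostaglandin synthase PTGS2 (121 TPM, log2 fold change 6.13) among those that rose. For cytokine genes camera gave adjusted p = 3.33e-06, and adjusted p = 0.658 with an estimated correlation. Interferon-stimulated genes went down, 29 of 45 lower and 1 higher (median log2 -1.43), IFITM1 (2.12 TPM, log2 fold change -6.83) among them. For interferon-stimulated genes camera gave adjusted p = 7.79e-05, and adjusted p = 0.733 with an estimated correlation. Growth factor and feedback genes of MAPK output went up, 13 of 26 higher and 2 lower (median log2 0.97), as in PHLDA1 (119 TPM, log2 fold change 4.06) and the EGF receptor ligand EREG (25.1 TPM, log2 fold change 4.17). For MAPK output camera gave adjusted p = 7.79e-05, and adjusted p = 0.656 with an estimated correlation. HOX genes, which set position along the body, counted 20 of 35 higher and 4 lower (median log2 1.35), HOXA9 rising from 9.85 to 83.9 TPM. For HOX genes camera gave adjusted p = 1.08e-06, and adjusted p = 0.0693 with an estimated correlation. Epithelial junction genes counted 13 of 34 lower and 0 higher (median log2 -0.79). For junction genes camera gave adjusted p = 0.00172, and adjusted p = 0.398 with an estimated correlation.

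Cell cycle genes were lower for 16 of 46 and higher for 1 (median log2 -0.60), which median-of-ratios scaling moved to 9 lower and 3 higher. For cell cycle genes camera gave adjusted p = 0.00867, and adjusted p = 0.658 with an estimated correlation. Fatty acid synthesis genes counted 5 of 21 higher, 2 lower (median log2 0.76), with FADS2 (349.8 TPM, log2 fold change 3.33), and 10 higher, 1 lower with that scaling. For fatty acid genes camera gave adjusted p = 0.0325, and adjusted p = 0.733 with an estimated correlation. Cancer-testis genes, normally silent outside the germ line, counted 4 of 15 higher and 0 lower (median log2 0.01). For cancer-testis genes camera gave adjusted p = 0.0026, and adjusted p = 0.0826 with an estimated correlation. Replication-dependent histone genes counted 6 of 33 higher and 3 lower (median log2 0.36). For histone genes camera gave adjusted p = 0.0411, and adjusted p = 0.658 with an estimated correlation. Their median was 0.78 log2 in the first 5637 library, which held 7.59% short RNA, and 0.12 and 0.25 in the others (1.63% and 1.70%). The histone call was lost with median-of-ratios scaling (adjusted p = 0.125) and without SV-HUC-1 replicate 1 (0.0991), SV-HUC-1 replicate 2 (0.0607), 5637 replicate 1 (0.116) or T24 replicate 3 (0.0559). The median of each called list lay on the side of the call in 3 of 3 libraries of 5637, except for the cancer-testis list (1 of 3, medians 0, 0.04 and 0). Counts adjusted over the list alone equalled those over all genes for every list but the cytokine one (21 higher, 3 lower).

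The luminal urothelial list (5 of 20 higher, 7 lower, adjusted p = 0.918, and 6 higher and 4 lower with median-of-ratios scaling) and the mesenchymal list (7 of 30 higher, 12 lower, adjusted p = 0.807) did not pass. MHC class I presentation (2 of 21 higher, 5 lower, adjusted p = 0.263) and p53 targets (4 of 33 higher, 6 lower, adjusted p = 0.551) did not pass. TGF-beta and YAP output (2 of 24 higher, 12 lower, adjusted p = 0.178) and hypoxia and glycolysis (2 of 32 higher, 8 lower, adjusted p = 0.33) did not pass. NRF2 targets (5 of 27 higher, 8 lower, adjusted p = 0.894) and the unfolded protein response (3 of 27 higher, 3 lower, adjusted p = 0.304) did not pass. Bladder cancer drivers (7 of 31 higher, 6 lower, adjusted p = 0.585) and nuclear oxidative phosphorylation (1 of 39 higher, 6 lower, adjusted p = 0.324, and 3 higher, 2 lower with median-of-ratios scaling) did not pass. Mitochondrially encoded genes (0 of 13 higher, 0 lower, adjusted p = 0.918, and 5 at an unadjusted p under 0.05 by limma) and the immune list (0 of 6 higher, 2 lower, adjusted p = 0.432) did not pass. The neuroendocrine list (0 of 6 higher, 2 lower, adjusted p = 0.775) did not pass. Cholesterol synthesis (3 of 25 higher, 0 lower, adjusted p = 0.0717) passed without 5637 replicate 3 (0.000599), and with the third library of every line left out 11 genes were higher. The protease list (11 of 35 higher, 10 lower, adjusted p = 0.219) passed without SV-HUC-1 replicate 1 (0.0464), 2 (0.0393) or 3 (0.0193), the androgen, oestrogen and retinoid list (8 of 19 higher, 5 lower, adjusted p = 0.103) without SV-HUC-1 replicate 2 (0.0373), and the fibroblast and muscle list (1 of 8 higher, 1 lower, adjusted p = 0.123) without SV-HUC-1 replicate 1 (0.0464), 2 (0.0499) or 3 (0.0419) or 5637 replicate 3 (0.0326). Of 3 endothelial genes 2 were lower, too few for a set test. Median, mean and test differed in sign for NRF2 targets, the unfolded protein response, drivers and mitochondrially encoded genes.

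In UMUC3, 34 of 34 epithelial junction genes were lower than in SV-HUC-1 (adjusted p = 0.0131 with an estimated correlation). Fibronectin FN1 (ENSG00000115414) fell furthest, from 7984 ± 1140 to 1.74 ± 0.665 TPM (log2 fold change -11.53, SE 0.66, adjusted p = 3.81e-09). The simple-epithelium keratin KRT19 (ENSG00000171345) fell next, from 2490 ± 404 to 0.44 ± 0.157 TPM (log2 fold change -10.75, SE 0.33, adjusted p = 6.93e-12). The cell cycle inhibitor stratifin SFN (ENSG00000175793) from 1092 ± 313 to 0.0667 ± 0.0577 TPM (log2 fold change -9.97, SE 0.23, adjusted p = 5.68e-13) and the keratin KRT17 (0.223 TPM, log2 fold change -9.77) fell too. The long noncoding RNA UCA1 (ENSG00000214049) fell from 616 ± 81.4 to 0.0167 ± 0.0289 TPM (log2 fold change -9.24, SE 0.43, adjusted p = 4.26e-10). The retinoic acid producing enzyme ALDH1A3 (ENSG00000184254) from 667 ± 72 to 0.123 ± 0.0577 TPM (log2 fold change -9.21, SE 0.40, adjusted p = 2.32e-10) and IFI27 (0.207 TPM, log2 fold change -9.49) fell as well. The protease inhibitor CST6 (ENSG00000175315) was at 635 ± 29.7 TPM in SV-HUC-1 and listed at 0 in UMUC3. The membrane protein EMP3 (ENSG00000142227) rose most, from 3.2 ± 0.558 to 1306 ± 18.6 TPM (log2 fold change 8.29, SE 0.25, adjusted p = 7.01e-12). The decoy receptor IL13RA2 (ENSG00000123496) rose from 0.0633 ± 0.11 to 232 ± 6.37 TPM (log2 fold change 7.78, SE 0.32, adjusted p = 1.25e-10). So did the neuropeptide precursor VGF (ENSG00000128564) from 1.11 ± 0.295 to 214 ± 15.8 TPM (log2 fold change 6.67, SE 0.22, adjusted p = 1.74e-11) and the carbonic anhydrase CA12 (105 TPM, log2 fold change 6.41). The cancer-testis antigen MAGEA4 (ENSG00000147381) was listed at 0 in SV-HUC-1 and at 136, 129 and 123 TPM in UMUC3. The near-identical copies MTCO2P2, RNU4-1 and RPSAP58 also rose and are uncertain, since reads could be split between copies.

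The tumour suppressor CDKN2A stood at 0, 0 and 0.32 TPM in the UMUC3 libraries against 379.6 ± 95.9 in SV-HUC-1 (log2 fold change -8.41, SE 0.22, adjusted p = 1.66e-12). The purine salvage gene MTAP (ENSG00000099810) from 20.6 ± 2.5 to 0.303 ± 0.0603 TPM (log2 fold change -4.05, SE 0.19, adjusted p = 4.8e-10) and the inhibitor gene CDKN2B (log2 fold change -4.19, SE 0.25, adjusted p = 5.22e-09) fell. The mesenchymal list did not pass (5 of 30 higher, 11 lower, adjusted p = 0.745), and FN1 fell as given above. Of its members VIM (ENSG00000026025) rose from 313 ± 164 to 2281 ± 31 TPM (log2 fold change 3.05, SE 0.35, adjusted p = 4.63e-06). The repressor ZEB1 (ENSG00000148516) rose from 0.040 ± 0.0458 to 12.6 ± 0.875 TPM (log2 fold change 3.71, SE 0.26, adjusted p = 2.73e-08). E-cadherin CDH1 and EPCAM were at 71.1 ± 5.28 and 255 ± 6.06 TPM in SV-HUC-1 and listed at 0 in UMUC3. The glycolytic gene GAPDH rose from 3443 to 16870 TPM (log2 fold change 2.29, SE 0.14, adjusted p = 1.01e-08). The telomerase gene TERT rose from 0.94 to 4.71 TPM (log2 fold change 1.61, SE 0.26, adjusted p = 0.000115).

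By group, 34 of 34 epithelial junction genes were lower and 0 higher (median log2 -5.1), among them the claudin CLDN7 (0.0133 TPM, log2 fold change -8.52) and EPCAM, listed at 0. For junction genes camera gave adjusted p = 3.22e-15, and adjusted p = 0.0131 with an estimated correlation. Luminal urothelial genes counted 14 of 20 lower and 0 higher (median log2 -2.64), basal and squamous genes 15 of 27 lower and 0 higher (median log2 -2.14). For luminal genes camera gave adjusted p = 5.61e-05, and adjusted p = 0.0693 with an estimated correlation. For basal genes camera gave adjusted p = 0.0068, and adjusted p = 0.485 with an estimated correlation. Interferon-stimulated genes were lower for 31 of 45 and higher for 0 (median log2 -1.85). For interferon-stimulated genes camera gave adjusted p = 0.00156, and adjusted p = 0.761 with an estimated correlation. Replication-dependent histone genes rose for 18 of 33 and fell for 0 (median log2 1.1), although their copies are alike and uncertain. For histone genes camera gave adjusted p = 2.83e-09, and adjusted p = 0.0819 with an estimated correlation. Short RNA held 3.96% to 4.16% of the TPM in UMUC3, 1.38% to 2.41% in J82 and 0.244% to 0.593% in T24, against 0.223% to 0.344% in SV-HUC-1. Cancer-testis genes rose for 6 of 15 (median log2 0.00), the median being 0 and the mean 2.09, and for 3 of 6 when the third library of every line was left out. For cancer-testis genes camera gave adjusted p = 3.43e-06, and adjusted p = 0.0131 with an estimated correlation. MAPK output counted 11 of 26 higher and 4 lower (median log2 0.51), with PHLDA1 (44.2 TPM, log2 fold change 2.65). For MAPK output camera gave adjusted p = 0.000459, and adjusted p = 0.658 with an estimated correlation. Of 6 neuroendocrine genes 3 were higher (median log2 0.84). For neuroendocrine genes camera gave adjusted p = 0.0068, and adjusted p = 0.278 with an estimated correlation.

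Cell cycle genes counted 23 of 46 lower and 1 higher (median log2 -1.03), MYBL2 (66.7 TPM, log2 fold change -2.83) among them, and 11 lower with median-of-ratios scaling. For cell cycle genes camera gave adjusted p = 0.00176, and adjusted p = 0.656 with an estimated correlation. The p53 targets counted 19 of 33 lower and 1 higher (median log2 -1.21), as in PLK2 (8.21 TPM, log2 fold change -4.23), and 12 lower with that scaling. For p53 targets camera gave adjusted p = 0.0118, and adjusted p = 0.614 with an estimated correlation. Unfolded protein response genes rose for 6 of 27 and fell for 1 (median log2 0.19), the stress factor DDIT3 (56.6 TPM, log2 fold change 2.94) among them, 11 with the scaling. For unfolded protein genes camera gave adjusted p = 0.00087, and adjusted p = 0.658 with an estimated correlation. Cholesterol synthesis counted 7 of 25 higher and 3 lower (median log2 0.57), which the scaling moved to 14 and 2. For cholesterol genes camera gave adjusted p = 0.00237, and adjusted p = 0.75 with an estimated correlation. Nuclear oxidative phosphorylation counted 7 of 39 higher and 3 lower (median log2 0.01), 13 and 0 with the scaling. For oxidative phosphorylation camera gave adjusted p = 0.00211, and adjusted p = 0.658 with an estimated correlation. Fatty acid synthesis counted 6 of 21 higher and 3 lower (median log2 0.09), with the lipid regulator SREBF1 (134 TPM, log2 fold change 2.79), and its call was lost with the scaling (adjusted p = 0.0539). For fatty acid genes camera gave adjusted p = 0.0347, and adjusted p = 0.733 with an estimated correlation. Bladder cancer drivers counted 16 of 31 lower and 2 higher (median log2 -1.1). For driver genes camera gave adjusted p = 0.0495, and adjusted p = 0.733 with an estimated correlation. This call was lost without 5637 replicate 1, 2 or 3 (adjusted p = 0.0572, 0.0529 and 0.0586), UMUC3 replicate 3 (0.0587), T24 replicate 1, 2 or 3 (0.0533, 0.055 and 0.0733) or J82 replicate 1 or 2 (0.051 and 0.0505).

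Of the called lists, the median lay on the side of the call in 3 of 3 UMUC3 libraries, except for fatty acid synthesis and nuclear oxidative phosphorylation (2 of 3 each) and the cancer-testis list (0 of 3, all medians 0). MHC class I presentation (0 of 21 higher, 6 lower, adjusted p = 0.913) and cytokine and NF-kB genes (5 of 35 higher, 12 lower, adjusted p = 0.633) did not pass. Hypoxia and glycolysis (7 of 32 higher, 9 lower, adjusted p = 0.138) and the protease list (7 of 35 higher, 15 lower, adjusted p = 0.894) did not pass. Mitochondrially encoded genes (0 of 13 higher, 5 lower, adjusted p = 0.17) and the immune list (3 of 6 higher, 2 lower, adjusted p = 0.387) did not pass. The fibroblast and muscle list (1 of 8 higher, 3 lower, adjusted p = 0.666) did not pass. With median-of-ratios scaling the hypoxia list counted 10 higher and 8 lower, the protease list 11 and 10, and no mitochondrially encoded gene was lower. TGF-beta and YAP output (2 of 24 higher, 14 lower, adjusted p = 0.0806) passed with that scaling (adjusted p = 0.0403) and without SV-HUC-1 replicate 2 (0.0458) or T24 replicate 3 (0.0362). NRF2 targets (7 of 27 higher, 5 lower, adjusted p = 0.0644) passed with it (0.0413, 10 higher and 0 lower) and without UMUC3 replicate 1 (0.0446), 2 (0.0415) or 3 (0.0423). The androgen, oestrogen and retinoid list (1 of 19 higher, 11 lower, adjusted p = 0.0511) passed with it (0.00738) and without SV-HUC-1 replicate 1 (0.0464), 5637 replicate 2 (0.048) or 3 (0.0476) or UMUC3 replicate 1 (0.0431). HOX genes (11 of 35 higher, 12 lower, adjusted p = 0.0643, and 14 higher, 9 lower with the scaling) passed without SV-HUC-1 replicate 1 (0.0281), 2 (0.0208) or 3 (0.0222), UMUC3 replicate 1 (0.0481) or 2 (0.0343) or J82 replicate 3 (0.0495). One endothelial gene was higher and 1 lower of 3. Median or mean differed in sign from the test for the mesenchymal, cytokine, hypoxia, NRF2, HOX and fibroblast lists. Counts adjusted over the list alone equalled those over all genes except for hypoxia and glycolysis (6 higher, 9 lower).

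In T24, 31 of 34 epithelial junction genes were lower than in SV-HUC-1 (adjusted p = 0.0131 with an estimated correlation). Of 35 cytokine genes 18 were higher and 6 lower, a call lost with an estimated correlation (adjusted p = 0.658). The granulocyte colony-stimulating factor CSF3 (ENSG00000108342) rose from 0.257 ± 0.10 TPM to 2801, 3331 and 449 TPM in the 3 libraries (log2 fold change 10.33, SE 0.54, adjusted p = 1.86e-09). The interleukin IL1B (ENSG00000125538) rose from 2.31 ± 2.3 to 815, 962 and 164 TPM (log2 fold change 7.47, SE 0.65, adjusted p = 3.74e-07). The lipolysis inhibitor G0S2 (ENSG00000123689) rose from 12.8 ± 2.34 to 1614 ± 71.9 TPM (log2 fold change 6.88, SE 0.40, adjusted p = 5.99e-09). EMP3 (539 TPM, log2 fold change 6.99) and IL13RA2 (202 TPM, log2 fold change 7.5) rose too. The metal-binding MT1E (ENSG00000169715) was listed at 0 in SV-HUC-1 and at 1144, 1138 and 1651 TPM in T24. LINC00989 and TCEAL8 were also listed at 0 in SV-HUC-1. The basal keratin KRT5 (ENSG00000186081) fell from 524 ± 113 to 0.193 ± 0.155 TPM (log2 fold change -8.77, SE 0.23, adjusted p = 3.6e-12). The keratin KRT19 (ENSG00000171345) from 2490 ± 404 to 5.31 ± 0.356 TPM (log2 fold change -8.61, SE 0.33, adjusted p = 8.22e-11) and its relative KRT17 (0.703 TPM, log2 fold change -9.28) fell. The hemidesmosome integrin ITGB4 (ENSG00000132470) fell from 329.9 ± 65.3 to 0.157 ± 0.118 TPM (log2 fold change -8.15, SE 0.37, adjusted p = 4.59e-10). The surface glycoprotein CD24 (0.050 TPM, log2 fold change -7.85) and the proteases KLK5 (0.060 TPM, log2 fold change -8.49) and KLK6 (0.0333 TPM, log2 fold change -8.38) fell as well, and CST6 was listed at 0.

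Among the cancer and urothelial genes fixed in advance, VIM rose from 313 to 4251 TPM (log2 fold change 3.94, SE 0.35, adjusted p = 4.69e-07). The transcription factor ZEB1 rose from 0.040 to 5.24 TPM (log2 fold change 2.54, SE 0.26, adjusted p = 1.72e-06). CDH1 fell from 71.1 to 0.020 TPM (log2 fold change -6.14, SE 0.26, adjusted p = 2.42e-10). EPCAM fell from 255 to 0.70 TPM (log2 fold change -7.24, SE 0.20, adjusted p = 4.82e-12). The urothelial transcription factor GATA3 fell from 43.9 to 0.217 TPM (log2 fold change -5.21, SE 0.21, adjusted p = 1.38e-10). The growth factor receptor FGFR3 changed by -1.58 log2 (adjusted p = 0.000357).

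By group, 31 of 34 epithelial junction genes were lower and 1 higher (median log2 -4.12). For junction genes camera gave adjusted p = 1.88e-14, and adjusted p = 0.0131 with an estimated correlation. Cytokine and NF-kB genes counted 18 of 35 higher and 6 lower (median log2 1.62). For cytokine genes camera gave adjusted p = 2.7e-05, and adjusted p = 0.658 with an estimated correlation. Their median over SV-HUC-1 was 2.39, 2.5 and 0.00 log2 in the 3 T24 libraries, and without T24 replicate 3, which stood apart, 22 were higher and 5 lower. Cancer-testis genes counted 12 of 15 higher and 0 lower (median log2 2.49), and 6 of 9 without T24 replicate 3, when fewer members passed the filter. For cancer-testis genes camera gave adjusted p = 1.53e-13, and adjusted p = 0.00237 with an estimated correlation. In 1 of the lines compared 12 of them were listed at 0, among them MAGEA3 and XAGE1A in SV-HUC-1, where MAGEA3 stood at 69.8, 64.4 and 102 TPM and XAGE1A at 52.9, 42 and 33.4 TPM in T24, both with near-identical copies that leave them uncertain. HOX genes counted 14 of 35 higher and 8 lower (median log2 0.74). For HOX genes camera gave adjusted p = 7.79e-05, and adjusted p = 0.128 with an estimated correlation. NRF2 targets, which handle oxidants, counted 9 of 27 higher and 2 lower (median log2 0.43), among them the haem oxygenase HMOX1 (409 TPM, log2 fold change 3.23) and the reductase AKR1C1 (29 TPM, log2 fold change 4.27). For NRF2 targets camera gave adjusted p = 9.25e-05, and adjusted p = 0.0375 with an estimated correlation. MAPK output counted 13 of 26 higher and 3 lower (median log2 0.99), with the chromatin factor HMGA2 (44.8 TPM, log2 fold change 4.21). For MAPK output camera gave adjusted p = 0.000734, and adjusted p = 0.658 with an estimated correlation.

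Cell cycle genes counted 21 of 46 lower and 0 higher (median log2 -0.86), MYBL2 (82.2 TPM, log2 fold change -2.56) among them, and 12 lower with median-of-ratios scaling. For cell cycle genes camera gave adjusted p = 9.61e-05, and adjusted p = 0.498 with an estimated correlation. Unfolded protein response genes counted 6 of 27 higher and 1 lower (median log2 0.34), with DDIT3 (88.6 TPM, log2 fold change 3.57), and 12 higher with that scaling and 10 without T24 replicate 3. For unfolded protein genes camera gave adjusted p = 0.000905, and adjusted p = 0.658 with an estimated correlation. Luminal urothelial genes counted 11 of 20 lower and 2 higher (median log2 -1.38), a call lost without SV-HUC-1 replicate 1 (adjusted p = 0.102), 2 (0.113) or 3 (0.118). For luminal genes camera gave adjusted p = 0.0144, and adjusted p = 0.398 with an estimated correlation. Mitochondrially encoded genes counted 8 of 13 lower and 0 higher (median log2 -1.15), which the scaling moved to 2 lower and an adjusted p of 0.0501. For mitochondrially encoded genes camera gave adjusted p = 0.0116, and adjusted p = 0.733 with an estimated correlation. Hypoxia and glycolysis counted 5 of 32 higher and 6 lower (median log2 0.02), with the aldolase ALDOC (39.3 TPM, log2 fold change 4.54). For hypoxia genes camera gave adjusted p = 0.0282, and adjusted p = 0.794 with an estimated correlation. It counted 11 higher and 2 lower with the scaling and 10 and 3 without T24 replicate 3, and its call was lost with the scaling (0.0542) and without SV-HUC-1 replicate 3 (0.0531), T24 replicate 1 (0.0867) or T24 replicate 2 (0.0619). The median lay on the side of the call in 3 of 3 T24 libraries for the called lists, except for hypoxia and the unfolded protein response (2 of 3 each), though by 0.00142 log2 alone for cytokine genes in the third.

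The mesenchymal list (9 of 30 higher, 13 lower, adjusted p = 0.75) and MHC class I presentation (1 of 21 higher, 7 lower, adjusted p = 0.37) did not pass. P53 targets (3 of 33 higher, 9 lower, adjusted p = 0.682, and 6 higher, 9 lower without T24 replicate 3) and TGF-beta and YAP output (0 of 24 higher, 10 lower, adjusted p = 0.246, and 3 higher, 10 lower without T24 replicate 3) did not pass. Bladder cancer drivers (2 of 31 higher, 11 lower, adjusted p = 0.151) and histone genes (0 of 33 higher, 11 lower, adjusted p = 0.703, and 7 lower with median-of-ratios scaling) did not pass. The fibroblast and muscle list (1 of 8 higher, 2 lower, adjusted p = 0.596) and the neuroendocrine list (1 of 6 higher, 1 lower, adjusted p = 0.913) did not pass. Among mesenchymal genes the collagens COL6A1 (401 TPM, log2 fold change 3.97) and COL5A2 (36 TPM, log2 fold change 4.6) rose. Interferon-stimulated genes (2 of 45 higher, 23 lower, adjusted p = 0.178, and 14 lower with the scaling) passed without J82 replicate 3 (0.0223). Basal and squamous genes (2 of 27 higher, 11 lower, adjusted p = 0.0549) passed with the scaling (adjusted p = 0.00833) and without SV-HUC-1 replicate 1 (0.0235) or 2 (0.0211), 5637 replicate 1 (0.0233), 2 (0.0211) or 3 (0.012) or T24 replicate 1 (0.0355) or 2 (0.048). Without T24 replicate 3, cholesterol synthesis (2 of 25 higher, 3 lower, adjusted p = 0.207) passed with 7 higher and 3 lower (0.0362) and fatty acid synthesis (5 of 21 higher, 3 lower, adjusted p = 0.0575) with 9 higher and 2 lower (0.00494). The immune list (3 of 6 higher, 1 lower, adjusted p = 0.157) passed without SV-HUC-1 replicate 1 (0.041), 2 (0.0134) or 3 (0.0329). The protease list (11 of 35 higher, 10 lower, adjusted p = 0.0587) passed without SV-HUC-1 replicate 1 (0.00663), 2 (0.00739) or 3 (0.00388), T24 replicate 3 (0.0118) or J82 replicate 3 (0.0388). Nuclear oxidative phosphorylation (0 of 39 higher, 1 lower, adjusted p = 0.178) passed without T24 replicate 2 (0.0429) and, with 6 higher and 0 lower, with the scaling (0.0351), which also passed the androgen, oestrogen and retinoid list (2 of 19 higher, 11 lower, adjusted p = 0.132) at 0.0424. One of 3 endothelial genes was higher. Median or mean differed in sign from the test for the mesenchymal, cholesterol, protease, oxidative phosphorylation and fibroblast lists. Counts adjusted over the list alone equalled those over all genes except for TGF-beta and YAP output (0 higher, 11 lower) and cholesterol synthesis (1 higher, 3 lower).

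In J82, 13 of 27 NRF2 targets were higher than in SV-HUC-1 and 32 of 34 epithelial junction genes lower (adjusted p = 0.0128 and adjusted p = 0.0131 with an estimated correlation). Of interferon-stimulated genes 28 of 45 and of MHC class I genes 13 of 21 were higher, calls lost with an estimated correlation (adjusted p = 0.624 and adjusted p = 0.614). The pregnancy-specific glycoprotein PSG1 (ENSG00000231924) rose most, from 1.21 ± 0.18 to 1482 ± 201 TPM (log2 fold change 9.38, SE 0.16, adjusted p = 7.85e-14). Its relative PSG9 (ENSG00000183668) from 0.92 ± 0.131 to 1059 ± 103 TPM (log2 fold change 9.11, SE 0.15, adjusted p = 7.85e-14) followed. Near-identical copies leave the split between PSG genes uncertain, and the same holds for the ribosomal RNA5S copies that also rose. The fibrillar collagen COL3A1 (ENSG00000168542) was listed at 0 in SV-HUC-1 and at 252, 255 and 112 TPM in J82. The matrix protein POSTN (ENSG00000133110) was listed at 0 in SV-HUC-1 and at 143, 132 and 458 TPM in J82. Stratifin SFN (ENSG00000175793) from 1092 ± 313 to 0.323 ± 0.211 TPM (log2 fold change -9.67, SE 0.23, adjusted p = 1.02e-12) and the noncoding RNA UCA1 (0.0333 TPM, log2 fold change -9.21) fell. The keratin KRT5 (ENSG00000186081) fell from 524 ± 113 to 0.147 ± 0.14 TPM (log2 fold change -8.83, SE 0.23, adjusted p = 2.34e-12). The tight junction protein CLDN7 (ENSG00000181885) fell from 371 ± 32.3 to 0.447 ± 0.307 TPM (log2 fold change -8.02, SE 0.24, adjusted p = 6.54e-12). The protease KLK5 (0.00667 TPM, log2 fold change -8.56) and the transporter SLC1A6 (0.00667 TPM, log2 fold change -7.76) fell too, and CST6 and KLK6 were listed at 0 in J82. FN1 fell from 7984 to 134 TPM (log2 fold change -5.92, SE 0.66, adjusted p = 4.72e-06).

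Of the same fixed genes, CDKN2A rose from 379.6 to 1701 TPM (log2 fold change 2.16, SE 0.22, adjusted p = 1.88e-06). CDH1 fell from 71.1 to 2.59 TPM (log2 fold change -4.42, SE 0.26, adjusted p = 6.77e-09). EPCAM fell from 255 to 0.407 TPM (log2 fold change -7.54, SE 0.20, adjusted p = 2.53e-12) and GATA3 from 43.9 to 0.417 TPM (log2 fold change -5.01, SE 0.21, adjusted p = 1.87e-10). ZEB1 rose from 0.040 to 3.79 TPM (log2 fold change 2.14, SE 0.26, adjusted p = 9.72e-06). VIM was at 521 ± 36.9 TPM, 0.92 log2 over SV-HUC-1 and under the 2-fold limit, which it passed with median-of-ratios scaling (1.29).

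By group, 28 of 45 interferon-stimulated genes were higher and 0 lower (median log2 1.45), among them IFI6 (1674 TPM, log2 fold change 4.02) and IFI44L (37.2 TPM, log2 fold change 4.46). For interferon-stimulated genes camera gave adjusted p = 4.96e-12, and adjusted p = 0.624 with an estimated correlation. Their median over SV-HUC-1 was 2.14, 2.09 and 0.42 log2 in the 3 J82 libraries, and without J82 replicate 3, which stood apart, 37 were higher and 0 lower. MHC class I presentation genes counted 13 of 21 higher and 0 lower (median log2 1.05), with the class I heavy chains HLA-B (ENSG00000234745) from 649 ± 352 to 4124 ± 364 TPM (log2 fold change 2.79, SE 0.48, adjusted p = 0.000272) and HLA-C (ENSG00000204525) from 599 ± 166 to 3261 ± 366 TPM (log2 fold change 2.47, SE 0.27, adjusted p = 3.95e-06). For MHC class I genes camera gave adjusted p = 5.61e-05, and adjusted p = 0.614 with an estimated correlation. NRF2 targets counted 13 of 27 higher and 1 lower (median log2 0.93), among them the reductases AKR1C3 (197 TPM, log2 fold change 7.13) and AKR1C1 (124 TPM, log2 fold change 6.31) and the cystine transporter SLC7A11 (42.5 TPM, log2 fold change 4.45). For NRF2 targets camera gave adjusted p = 3.31e-08, and adjusted p = 0.0128 with an estimated correlation. Cytokine and NF-kB genes counted 12 of 35 higher and 3 lower (median log2 0.33), as in the chemokine CCL5 (66.9 TPM, log2 fold change 3.5) and the growth factor CSF1 (75.4 TPM, log2 fold change 3.59). For cytokine genes camera gave adjusted p = 0.00473, and adjusted p = 0.761 with an estimated correlation. Epithelial junction genes counted 32 of 34 lower and 0 higher (median log2 -4.33), and basal and squamous genes 14 of 27 lower and 2 higher (median log2 -1.05). For junction genes camera gave adjusted p = 1.88e-14, and adjusted p = 0.0131 with an estimated correlation. For basal genes camera gave adjusted p = 0.00435, and adjusted p = 0.461 with an estimated correlation. The p53 targets counted 13 of 33 lower and 0 higher (median log2 -0.52), BTG2 (0.473 TPM, log2 fold change -3.89) among them. For p53 targets camera gave adjusted p = 0.0344, and adjusted p = 0.658 with an estimated correlation. Fatty acid synthesis counted 8 of 21 higher and 1 lower (median log2 0.63), as in SREBF1 (154 TPM, log2 fold change 2.86) and ELOVL6 (14.9 TPM, log2 fold change 2.59). For fatty acid genes camera gave adjusted p = 0.0026, and adjusted p = 0.658 with an estimated correlation.

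Luminal urothelial genes counted 10 of 20 lower and 1 higher (median log2 -1.18), and the call was lost without SV-HUC-1 replicate 1 (adjusted p = 0.0721), 2 (0.0878) or 3 (0.0809) or J82 replicate 3 (0.0596). For luminal genes camera gave adjusted p = 0.00974, and adjusted p = 0.346 with an estimated correlation. Histone genes counted 10 of 33 higher and 4 lower (median log2 0.53), not called with median-of-ratios scaling (0.0658), with short RNA above SV-HUC-1 as given for UMUC3. For histone genes camera gave adjusted p = 0.0118, and adjusted p = 0.656 with an estimated correlation. Cell cycle genes counted 14 of 46 lower and 2 higher (median log2 -0.68), 7 lower and not called with that scaling (0.193). For cell cycle genes camera gave adjusted p = 0.0479, and adjusted p = 0.733 with an estimated correlation. That cell cycle call was also lost without SV-HUC-1 replicate 3 (0.0639), 5637 replicate 2 (0.0515), UMUC3 replicate 1, 2 or 3 (0.0507, 0.0524 and 0.0533), T24 replicate 1 (0.0528) or J82 replicate 3 (0.162), and the replication gene MCM2 (417 TPM, log2 fold change 1.59) rose against it. Cholesterol synthesis counted 4 of 25 higher and 1 lower (median log2 0.43), 9 and 1 with the scaling and 8 and 1 without J82 replicate 3, and was not called without SV-HUC-1 replicate 1 (0.0502) or J82 replicate 1 (0.084) or 2 (0.0762). For cholesterol genes camera gave adjusted p = 0.0262, and adjusted p = 0.794 with an estimated correlation. Fibroblast and muscle genes counted 4 of 8 higher and 2 lower (median log2 1.24), the median without members at 0 in one line being -0.31. For fibroblast genes camera gave adjusted p = 0.0126, and adjusted p = 0.485 with an estimated correlation. Without J82 replicate 1, 2 or 3 this call was lost (0.978, 0.801 and 0.867, the first and second in the other direction), and without J82 replicate 3 it counted 1 higher and 2 lower of 5. The median lay on the side of the call in 3 of 3 J82 libraries for every called list but cholesterol synthesis (2 of 3).

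The mesenchymal list (10 of 30 higher, 11 lower, adjusted p = 0.138, and 12 higher, 9 lower with median-of-ratios scaling) and MAPK output (6 of 26 higher, 3 lower, adjusted p = 0.245) did not pass. TGF-beta and YAP output (3 of 24 higher, 8 lower, adjusted p = 0.971) and hypoxia and glycolysis (3 of 32 higher, 11 lower, adjusted p = 0.918) did not pass. The unfolded protein response (2 of 27 higher, 4 lower, adjusted p = 0.138, and 5 higher, 2 lower with the scaling) and HOX genes (6 of 35 higher, 6 lower, adjusted p = 0.37, and 8 higher, 5 lower with it) did not pass. The protease list (7 of 35 higher, 9 lower, adjusted p = 0.585, and 9 higher, 8 lower with it) and the androgen, oestrogen and retinoid list (2 of 19 higher, 9 lower, adjusted p = 0.157) did not pass. Bladder cancer drivers (3 of 31 higher, 6 lower, adjusted p = 0.913, and 10 lower without J82 replicate 3) and mitochondrially encoded genes (0 of 13 higher, 0 lower, adjusted p = 0.797, and 2 at an unadjusted p under 0.05 by limma) did not pass. The neuroendocrine list (3 of 6 higher, 1 lower, adjusted p = 0.219, and 1 higher, 1 lower without J82 replicate 3) did not pass. Among mesenchymal genes COL1A2 (43.3 TPM, log2 fold change 5.37) and COL5A2 (69.6 TPM, log2 fold change 5.82) rose, and the proteoglycan LUM, at 0 in SV-HUC-1, stood at 67, 67 and 80.9 TPM. Nuclear oxidative phosphorylation (3 of 39 higher, 3 lower, adjusted p = 0.103) passed with the scaling (adjusted p = 0.0351). By limma 0 of 15 cancer-testis genes were called and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.109). The immune list (2 of 6 higher, 1 lower, adjusted p = 0.199) passed without SV-HUC-1 replicate 1 (0.0468) or 2 (0.0207). One of 3 endothelial genes was lower. Median or mean differed in sign from the test for MAPK output, TGF-beta and YAP output, hypoxia, the unfolded protein response, HOX, protease, oxidative phosphorylation and mitochondrially encoded genes. Counts adjusted over the list alone differed from those over all genes for epithelial junction (1 higher, 32 lower), cytokine (10 and 3), hypoxia (3 and 12) and cholesterol genes (3 and 1).

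**Figure D2:**
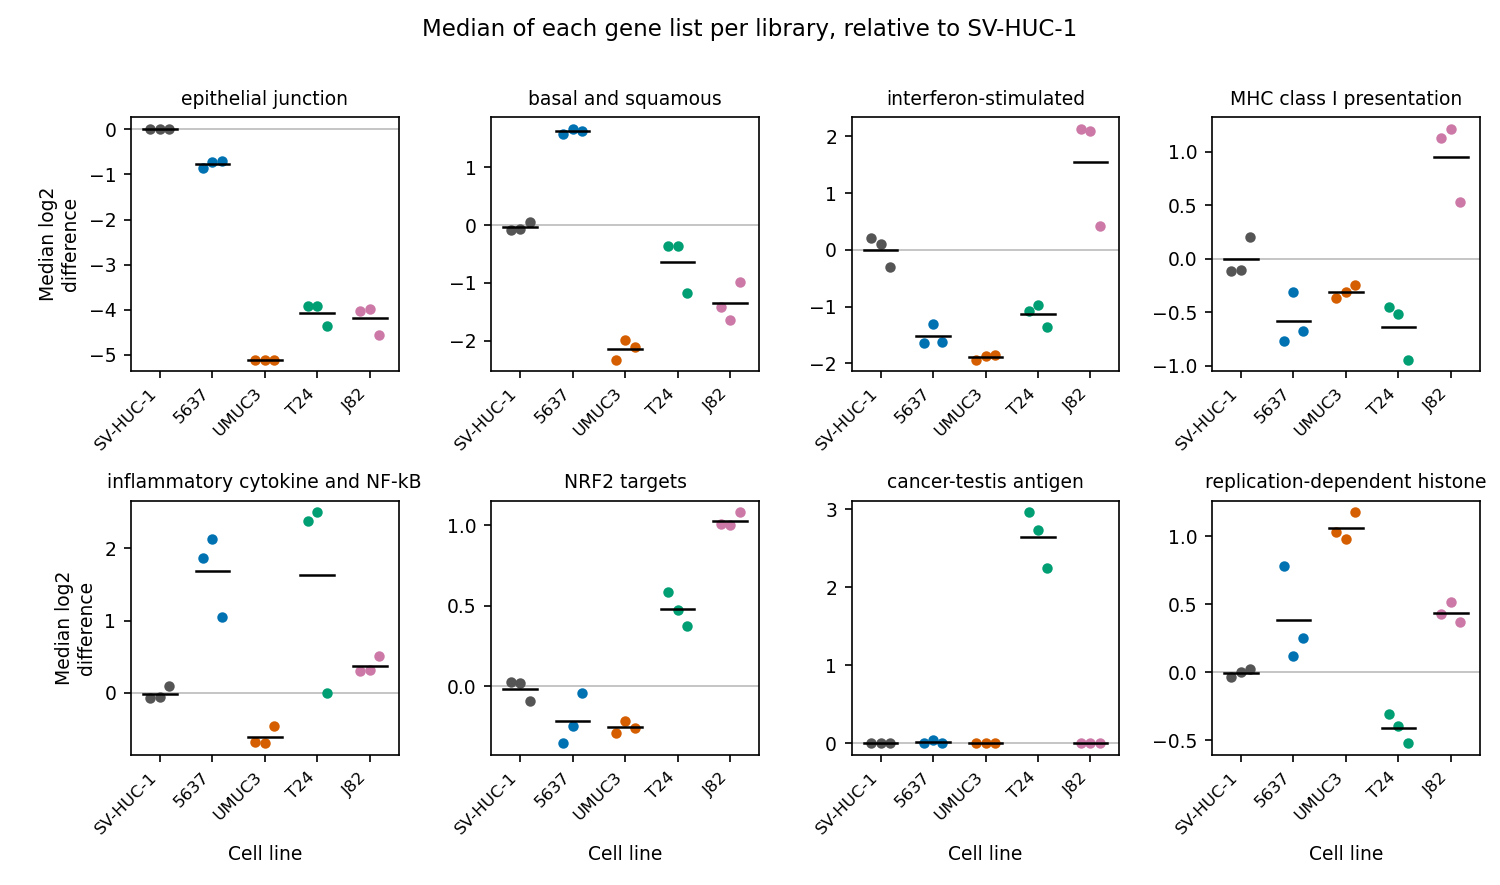
Median log2(TPM + 1) of 8 gene lists per library, as the difference in log2 units from the SV-HUC-1 mean, for the 5 cell lines. Points are libraries and black bars the mean of 3; interferon-stimulated genes lay at 2.14, 2.09 and 0.42 in the J82 libraries and cytokine genes at 2.39, 2.5 and 0.00 in the T24 libraries.

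Over the 4 comparisons with SV-HUC-1, 49 of 108 list tests by camera were called with the preset correlation of 0.01, and 7 of these also with an estimated correlation: epithelial junction genes in UMUC3, T24 and J82, cancer-testis genes in UMUC3 and T24, and NRF2 targets in T24 and J82. The cancer-testis calls are limited: 15 of 42 members passed the filter, for which a high level in 1 cancer line is enough, and their means in SV-HUC-1 were at most 0.0567 TPM (MAGEA2B), so the test against SV-HUC-1 could only show a rise.

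In all 4 cancer lines 136 genes were higher and 958 lower, the genes lowest and highest in SV-HUC-1. The membrane peptidase MME (ENSG00000196549) had a mean of 0.603 TPM in SV-HUC-1 and 13, 73.5, 48.7 and 35 TPM in 5637, UMUC3, T24 and J82, and the ganglioside synthase B4GALNT1 (ENSG00000135454) 1.92 TPM in SV-HUC-1 against 18.6, 26.4, 20.01 and 32.8 in the same order. The caveola protein CAVIN3 stood at 20.8 TPM in SV-HUC-1 against 166, 269, 331 and 127, the Wnt secretion factor WLS at 12.1 TPM in SV-HUC-1 against 86, 87.5, 54 and 56.7, the transcription factor STAT6 at 10.7 TPM in SV-HUC-1 against 45.9, 68.6, 123 and 108 and the adenosine-producing nucleotidase NT5E at 13 TPM in SV-HUC-1 against 59.9, 96.1, 57.6 and 49.3. TCEAL8 and PICSAR were listed at 0 in SV-HUC-1 and had means of 82.4, 48.5, 109 and 72.3 TPM and of 33.6, 79.8, 52.2 and 46.3 TPM in the cancer lines. RPSAP58, a pseudogene with near-identical copies, is uncertain. Lower in each line were KLK5, KLK6, SLC1A6, CST6 and KRT81, described above. The urothelial plaque protein UPK1B (ENSG00000114638) stood at 62.1, 62.6 and 40.2 TPM in SV-HUC-1 and was listed at 0 in 5637, T24 and J82, and the transcription cofactor VGLL1, at 65.4 ± 14.2 TPM in SV-HUC-1, was listed at 0 in UMUC3, T24 and J82. MAL (203 ± 17.5 TPM) and the prostacyclin synthase PTGIS (139 ± 57.7 TPM) were listed at 0 in 5637, MAL also in UMUC3, and lower in the others. The placental phosphatase ALPP and CPZ were lower in each line too.

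Independent lists of these sizes would share 1.12 higher and 42.3 lower genes, and 20 simulations of unchanged groups against the same controls gave 0. The simulation leaves out real effects and the independent value the shared controls. The excess may come from SV-HUC-1, and 3 control libraries are too few to split. With median-of-ratios scaling 276 genes were higher in each line and 552 lower. Another 807 genes were called in opposite directions in different lines, of 10496 called in any line. The fold changes of the line pairs correlated across genes at r = 0.417 (5637 and J82) to 0.614 (UMUC3 and T24), against 0.496 to 0.501 in the simulations. Their covariance exceeded the simulated one by 0.624 (5637 and J82) to 1.08 (UMUC3 and T24). The pair UMUC3 and T24 had 3129 genes called in one direction and 163 in opposite directions, where independent lists would share 1273 in one direction, and 5637 and J82 had 2003, 304 and 757.

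**Figure D3:**
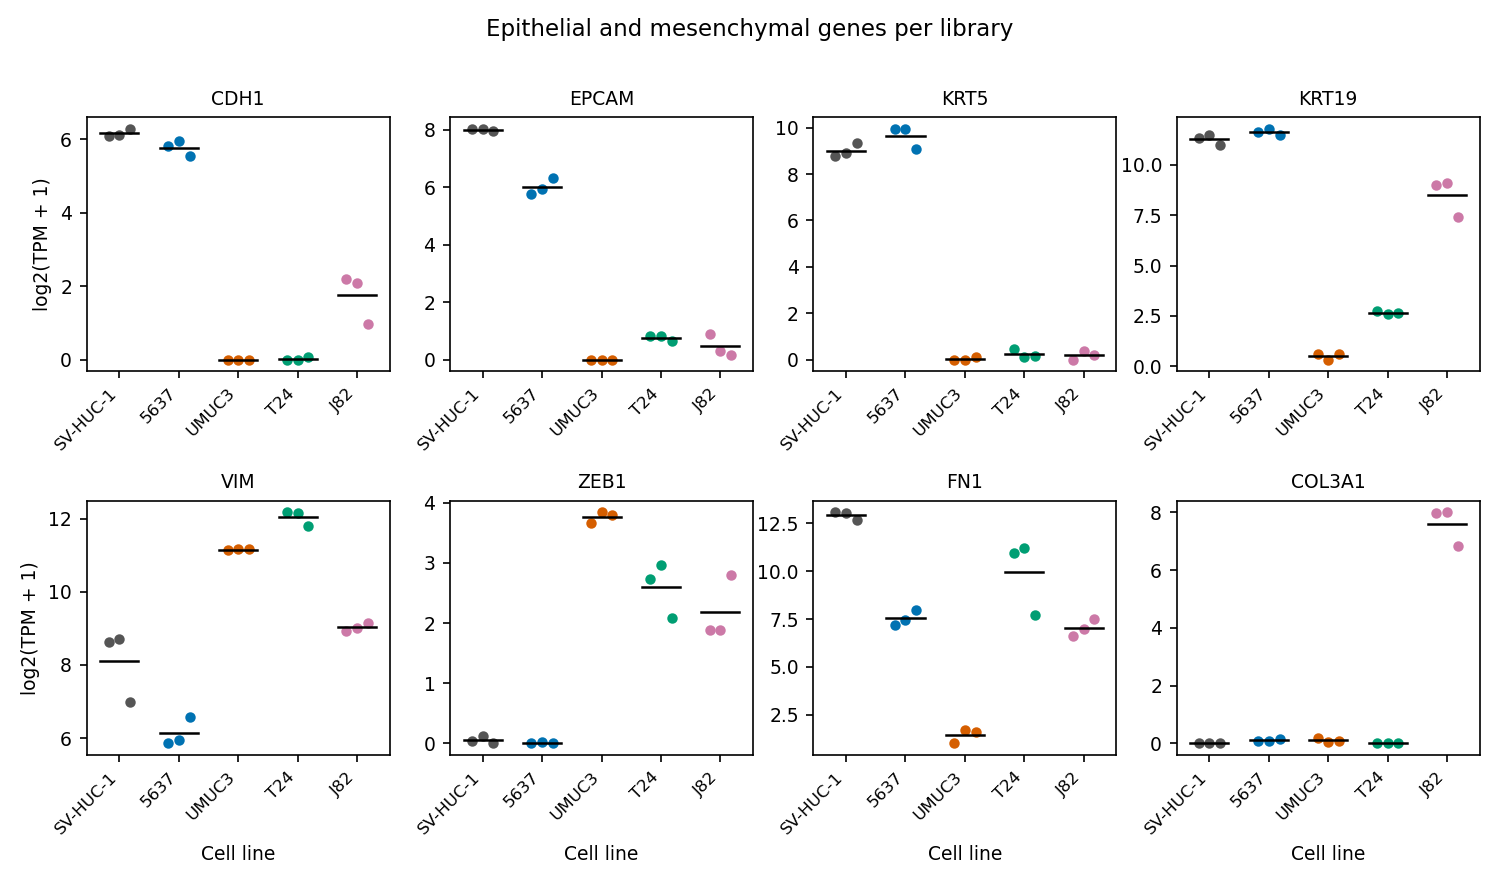
Expression of 4 epithelial genes (CDH1, EPCAM, KRT5, KRT19) and 4 mesenchymal genes (VIM, ZEB1, FN1, COL3A1) as log2(TPM + 1) in each library of the 5 cell lines. Points are libraries and black bars the mean of 3; CDH1 averaged 71.1 TPM in SV-HUC-1, 53.5 in 5637 and 0.020 in T24 and was listed at 0 in UMUC3.

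Compared directly, 5637 had more epithelial and basal transcripts than the other cancer lines. Epithelial junction genes were higher in 5637 than in UMUC3 for 32 of 34 (camera adjusted p = 3.88e-14, adjusted p = 0.0294 with an estimated correlation), than in T24 for 30 (camera adjusted p = 1.62e-13, adjusted p = 0.0294 with an estimated correlation) and than in J82 for 29 (camera adjusted p = 5.09e-12, adjusted p = 0.0301 with an estimated correlation). Basal and squamous genes were higher for 25 of 27 against UMUC3 (camera adjusted p = 7.25e-12, adjusted p = 0.0301 with an estimated correlation), 22 against T24 (camera adjusted p = 1.49e-10, adjusted p = 0.0386 with an estimated correlation) and 24 against J82 (camera adjusted p = 1.33e-12, adjusted p = 0.0294 with an estimated correlation). Interferon-stimulated genes were higher in J82 than in 5637 for 43 of 45 (camera adjusted p = 2.2e-18, adjusted p = 0.409 with an estimated correlation), than in UMUC3 for 44 (camera adjusted p = 1.72e-14, adjusted p = 0.46 with an estimated correlation) and than in T24 for 40 (camera adjusted p = 2.88e-13, adjusted p = 0.491 with an estimated correlation). MHC class I presentation genes were higher in J82 than in T24 for 14 of 21 (camera adjusted p = 5.27e-07, adjusted p = 0.409 with an estimated correlation), than in 5637 for 13 (camera adjusted p = 2.12e-06, adjusted p = 0.412 with an estimated correlation) and than in UMUC3 for 13 (camera adjusted p = 0.000193, adjusted p = 0.511 with an estimated correlation). NRF2 targets were higher in J82 than in 5637 for 16 of 27 and lower for 2 (camera adjusted p = 5.54e-07, adjusted p = 0.0258 with an estimated correlation), and higher in T24 than in 5637 for 14 and lower for 5 (camera adjusted p = 2e-04, adjusted p = 0.0419 with an estimated correlation). Histone genes were higher in UMUC3 than in T24 for 29 of 33 (camera adjusted p = 2.02e-12, adjusted p = 0.0455 with an estimated correlation). In all, 73 of 162 list tests between cancer lines were called and 12 of these also with an estimated correlation. With each library left out, the calls named here were kept at the preset correlation, and the estimated one was not rerun.

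Genes called against the other 4 lines in one direction were set apart. They were 640 highest and 186 lowest in 5637, 401 and 658 in UMUC3, 317 and 172 in T24, and 517 and 247 in J82. SV-HUC-1 itself had 958 and 136, the shared genes above. The count highest in UMUC3 was 258, 241 and 242 without UMUC3 replicate 1, 2 or 3, where genes of UMUC3 alone fail the filter. Median-of-ratios, upper-quartile and quantile scaling gave 618, 744 and 645, the last 2 with 407 and 393 lowest. Highest in UMUC3 were VGF, MAGEA4 and the neurotensin receptor NTSR1 (44.8 ± 2.67 TPM), and highest in T24 were MT1E and the decoy receptor TNFRSF6B (210.4 ± 2.31 TPM). Lowest in 5637 were the proteoglycan SRGN (88.1 TPM in SV-HUC-1, 0.020 in 5637) and SPARC. Lowest in UMUC3 were the oxidase subunit CYBA (882 TPM in SV-HUC-1, 0.593 in UMUC3), the peroxiredoxin PRDX2 (562 and 0.20) and the collagen chaperone SERPINH1 (242 and 0.163). Lowest in T24 were the gelatinase MMP2 (35 and 0.0533) and the matrix protein TGFBI (403 and 2.36), and lowest in J82 the aminotransferase OAT (100.2 and 0.213).

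**Figure D4:**
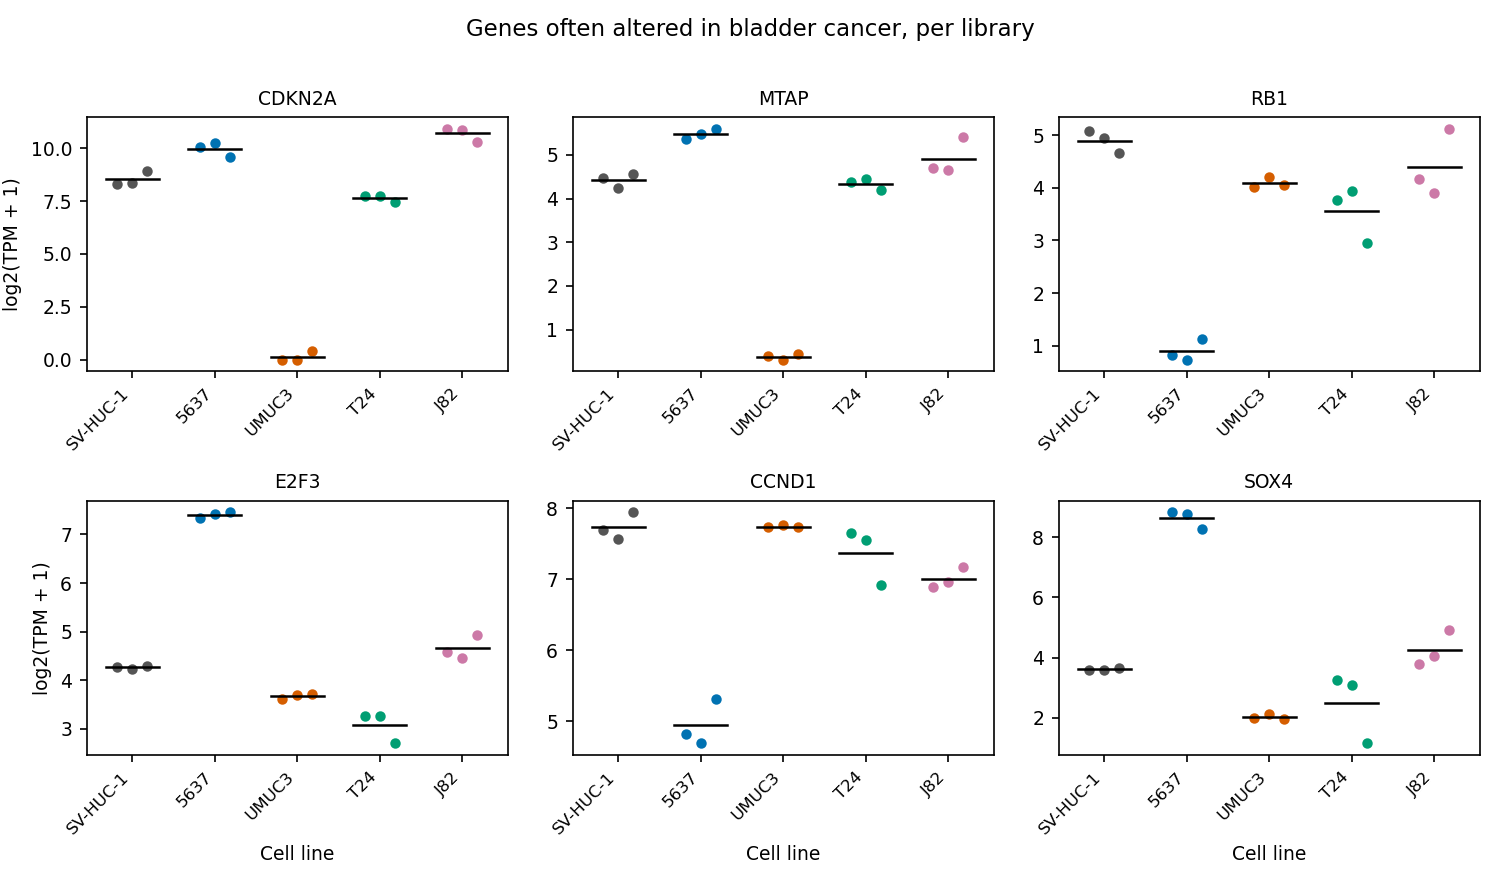
Expression of CDKN2A, MTAP, RB1, E2F3, CCND1 and SOX4 as log2(TPM + 1) in each library of the 5 cell lines. Points are libraries and black bars the mean of 3; CDKN2A averaged 0.107 TPM in UMUC3 and RB1 0.873 in 5637.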

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

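All explanations below were given their bounds before the values were seen, except the bootstrap interval of the mixed RNA share and its comparison with the share needed, which were added afterwards. Lines moved in opposite directions from SV-HUC-1 in these lists, and the difference itself passed the test between the lines. Basal and squamous genes had a median of 1.48 log2 in 5637 and -2.14 in UMUC3 (camera adjusted p = 7.25e-12, adjusted p = 0.0301 with an estimated correlation), and of 1.48 in 5637 and -1.05 in J82 (1.33e-12, and 0.0294 with an estimated correlation). Interferon-stimulated genes had a median of -1.43 log2 in 5637 and 1.45 in J82 (2.2e-18, adjusted p = 0.409 with an estimated correlation), and of -1.85 in UMUC3 and 1.45 in J82 (1.72e-14, adjusted p = 0.46 with an estimated correlation). In each of the 3 lines concerned the median lay on that side in 3 of 3 libraries. No biological explanation of these differences was tested.

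Interferon-stimulated genes were lower in the third J82 library than in the first and second, by a median of -1.65 log2, with 45 of 45 lower and 37 lower by 2-fold or more. Scaling of the whole library was argued against, since the median of all genes differed by 0.161 in the other direction. RNA of another line as the whole cause would have to make up 68% of the library, and this was argued against: genes that J82 lacks gained a median of 3.99% of the other lines' level (bootstrap interval 1.94 to 6.44, 291 genes), and 324 genes highest in J82 stood at a median of 0.82 of their level in its other libraries. Whether a few percent of other RNA may be present stays open, as the interval reaches past the 5% bound. Culture conditions stay open too, as the labels give no culture dates.

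Cytokine and NF-kB genes were lower in the third T24 library than in the first and second, by a median of -2.23 log2, with 35 of 35 lower and 29 lower by 2-fold or more. Genes that T24 lacks gained 0.00976% of the other lines' level (bootstrap interval 0 to 0.554, 158 genes), where 78.7% was needed. This argues against RNA of another line. But 289 genes highest in T24 stood at a median of 0.502 of their level in its other libraries, as dilution would give. The median of all genes differed by -0.178, which argues against scaling of the whole library. A culture difference stays open and was not tested.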

How the results depend on the processing

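The scalings of TPM, quantile normalization, treat, the filter on mean TPM and the omission of the third libraries were chosen after seeing the data. No alternative turned a called gene into a call in the other direction. Leaving out each library kept all 165 counts of calls within 1.5 times, with ranges of 1405 to 1643 higher and 2426 to 3027 lower genes in 5637, 1234 to 1475 and 4372 to 4988 in UMUC3, 1144 to 1627 and 3281 to 4045 in T24, 1427 to 1562 and 2995 to 4036 in J82, 121 to 163 and 672 to 992 shared, and 2930 to 3150 set apart. Other settings left 108 counts within 1.5 times and moved 57. The filters on low values, protein-coding genes only, fits of the 2 lines compared, and an adjusted p under 0.01 moved none of these by more. Of the counts set apart per line, other settings left 85 within 1.5 times and moved 35. With no fold filter they were 605 to 1244 highest and 501 to 1595 lowest per line, at 4-fold or more 105 to 206 and 35 to 178, and with a pseudocount of 5, 172 to 372 and 40 to 287. A pseudocount of 0.1 gave 340 to 1157 lowest, treat 94 lowest in T24, and omission of the third libraries 191 highest in UMUC3.

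With median-of-ratios scaling 2576 genes were higher and 2790 lower in UMUC3, 2231 and 2398 in T24, 2277 lower in J82, and 276 higher and 552 lower in all 4 lines. Upper-quartile scaling gave 3105 and 2372 in UMUC3, 2505 and 2156 in T24, 2568 and 1999 in J82, and 317 and 486 in all 4. Quantile normalization gave 2792 and 2512 in UMUC3, 2302 and 2192 in T24, 2162 lower in J82, and 294 and 527 in all 4. These scalings move the median of all genes by construction. Of the 136 and 958 shared genes, 136 and 552, 136 and 486, and 135 and 522 were kept under these scalings in turn. Treat against a fold of 1.5 left 72 higher in all 4. With no fold filter 2884 genes were higher and 5163 lower in 5637, 2408 and 7706 in UMUC3, 2450 and 6531 in T24, 2663 and 6136 in J82, 365 and 2210 in all 4, and 6757 set apart. At 4-fold or more these were 570 and 773, 462 and 1563, 469 and 1160, 529 and 1111, 23 and 235, and 929. A pseudocount of 0.1 gave 235 higher in all 4. A pseudocount of 5 gave 900 and 1483 in 5637, 768 and 2716 in UMUC3, 781 and 1877 in T24, 904 and 1773 in J82, 46 and 436 in all 4, and 1530 set apart, since it shrinks the changes of low genes.

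Of the list tests, 1292 kept their side under other settings, 151 lost the call, 118 gained it and 9 were reversed, all of these under fry, which does not compare a list with other genes. Reversed with fry were the protease list in 5637 (adjusted p = 0.00392), T24 (0.000217) and J82 (0.000186), the mesenchymal list in UMUC3 (9.36e-06) and T24 (1.55e-06), the fibroblast list in UMUC3 (0.0354), and, between lines, TGF-beta and YAP output for 5637 and UMUC3 (0.00235), and p53 targets (0.00428) and proteases (0.0151) for 5637 and T24. Leaving out libraries kept 3877 list tests, lost 69, gained 72 and reversed 2, both of them the fibroblast list in J82, whose adjusted p ran from 0.00254 to 0.978 (0.801 without J82 replicate 2). Of the named genes' values 9648 stayed called or uncalled, 504 lost the call and 34 gained it, and with libraries left out 9966, 124 and 14. The cause was not tested.

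The replicate numbers were not taken to pair the libraries, which needed every correlation over 0.1: over 30 pairs of same-numbered libraries the deviations correlated across genes at -0.213 to 0.263, with 3 pairs over 0.1 (5637 and J82 at 0.263 for number 3 and 0.177 for number 2, 5637 and T24 at 0.142 for number 3), and 6 of 15 libraries had their best partner under their own number. Cholesterol synthesis genes had a median over SV-HUC-1 of -0.27, -0.70 and -0.16 log2 in the third libraries of 5637, T24 and J82, against 0.41 to 0.93 in the first and second, so a condition shared by these libraries stays open. With the replicate block 1626 genes were higher and 2870 lower in 5637, 1466 and 4905 in UMUC3, 1368 and 3871 in T24, and 1553 and 3473 in J82. Planned tests on counts (edgeR with TMM factors, DESeq2, voom and the count filters) were not run, since the values are TPM. TPM keeps no depth, so how far depth limits the low genes is unknown.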

Other observations

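The tests of abundant genes and of neighbouring genes, with their thresholds, were chosen only after the result was seen, and the genes named beside the runs were picked after their values were seen. Further named genes changed in single comparisons. In UMUC3 the thioredoxin inhibitor TXNIP (143 TPM in SV-HUC-1, 4.09 in UMUC3, log2 fold change -4.73) fell while the lipid phosphatase LPIN1 (3.92 TPM in SV-HUC-1, 77.9 in UMUC3, log2 fold change 4.04) rose. In J82 the stress-induced DDIT4 (532 TPM in SV-HUC-1, 22.1 in J82, log2 fold change -4.79) fell and the growth factor TGFB2 (5.65 TPM in SV-HUC-1, 112 in J82, log2 fold change 4.17) rose. In 5637 the transcription factor KLF5 (30.2 TPM in SV-HUC-1, 216 in 5637, log2 fold change 2.8) rose.

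In 5637 a run of genes, neighbours in the sense defined below, stood high together. E2F3 was at 160.0 to 174 TPM against at most 29.7 elsewhere, CDKAL1 at 67.1 to 72 against 15.5 and SOX4 at 309.8 to 450.1 against 29.3, while ID4 (0.16 to 1.39) and MBOAT1 (3.36 to 4.33) were not raised. Another run held VHL (161 to 239), IRAK2 (144 to 268) and TATDN2 (127 to 145). In UMUC3 the neighbours MTAP (0.31, 0.24 and 0.36) and CDKN2A (0, 0 and 0.32) were near 0, as was CDKN2B (0, 0 and 0.060), but not KLHL9 (8.8, 8.43 and 9.44). NXT2, ACSL4 and TMEM164, and MYO1D and TMEM98, were near 0 in UMUC3 too.

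A candidate explanation is the gain or loss of a stretch of DNA, tested by counting neighbouring pairs against 10000 shuffles of gene order, adjusted over 8 tests. Among genes at least 4 times higher than in any other line and at 10 TPM or more, 5637 had 13 pairs of different families as sorted by gene symbol (1 of them, PI3 and SLPI, belongs to 1 family all the same) where shuffles averaged 2.67 and reached 10 (p = 1e-04 by permutation, the smallest that the shuffles can give, and adjusted p = 8e-04). Among genes under 0.5 TPM in UMUC3 and at 5 or more elsewhere, UMUC3 had 4 pairs against 0.827 (highest 6, adjusted p = 0.0372). J82 raised (5 pairs, 0.0717) and T24 raised (2 pairs, 0.25) did not pass, and there were 0 pairs among genes raised in UMUC3 or lost in 5637, T24 or J82 (adjusted p = 1 each). A first version with any pair gave 24 pairs in 5637 (4e-04), 4 in UMUC3 (0.0325), 20 in J82 (4e-04) and 3 in T24 (0.0466). It was restricted to different families after gene clusters had been seen in it, which ended the T24 result, and a later correction of how gene names are sorted into families ended that of J82. Shared regulation of neighbours can give such runs as well, and no copy number was measured.

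More genes were lower than higher in each cancer line. Gene length alone was argued against, with at most 37.33% higher calls over 12 combinations of line and length. So was loss of scarce genes (at most 35.7% from 10 TPM). As a part, length stays open: shares fell from short to long genes in T24 (29.52% to 22.66%) and UMUC3, hardly in 5637 or J82. Abundant genes may take more TPM. The top 200 held 40.3% in SV-HUC-1 and 43.6%, 52.8%, 45.6% and 42.8% in 5637, UMUC3, T24 and J82. That change matched 47.1%, 67.9% and 37.2% of the median shift in 5637, UMUC3 and T24 (67.2%, 74.4% and 72.9% with the share 1 SD higher), between or astride bounds of 50% and 75%, so it cannot be told apart there. In J82 it matched 20.6% (29.5%), which argues against it as the whole cause.

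Regrouping the libraries gave these counts. Of the 10 splits of 6 libraries the real one gave the most calls, 1 split as large in each comparison, with 4493 in 5637 (highest other 6), 6366 in UMUC3 (1), 5237 in T24 (2) and 5026 in J82 (27), and 10 splits are too few for a share under 0.05. Of 100 splits of the 15 libraries into groups of 3, 2 gave as many genes higher in all lines as the real 136. The other of these gave 464, several times the real count, and what produced it was not tested. For the 958 genes lower in all lines (highest other 335) and the 3138 set apart (868) it was 1 split. These splits break up the lines, whose own libraries resemble each other, so the shares show only that the lines differ. They cannot decide whether the cancer lines share a change or SV-HUC-1 alone stands apart. For the 136 genes no conclusion on chance is drawn, given the split with 464. For list calls 7 splits reached the real 49 against SV-HUC-1 (highest 52) and 5 the real 73 between lines (highest 84), so chance was not excluded, and these numbers move by a few splits with the draw.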
